A study of Homo sapiens with 9 samples.

How the data were processed

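Total RNA was measured by RNA-seq in 9 libraries of U2OS cells, 3 per group, made from 3 µg of RNA with a NEBNext Ultra RNA kit, per the labels' protocols. The labels do not state strand, so reads from overlapping antisense genes cannot be told apart. The authors deposited whole-number read counts per gene for each library, not normalised. Per the submitters' processing notes, HISAT2, HTSeq and DESeq2 were used with the hg38 build; versions and settings are not given in the sources used here. Each file listed 58721 gene identifiers, all found in GENCODE release 29, whose coordinates (GRCh38) and names were used. Between 66.3% and 67.1% of the reads in the files were counted on genes. The 5 entries that name no gene stayed out of library sizes and tests: 13.3% to 14.0% of reads overlapped no gene, 8.04% to 8.38% were ambiguous, 5.32% to 5.53% did not align uniquely, 3.79% to 4.65% had a low alignment quality and 1.68% to 2.26% were not aligned. Gene counts summed to 14851846 to 25375734 per library.

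Genes were filtered with filterByExpr over the 3 groups, leaving 19983, scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood F tests (R 4.3.3) on 1 fit of all 9 libraries with a term per group. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 in each of 3 contrasts. SE was the log2 fold change divided by the root of the F statistic, and CPM values were scaled by TMM. The common biological coefficient of variation was 4.68%. The 29 gene lists were fixed before the data were examined, as were the main tests, the rule for named genes and all but 2 of the alternatives. They were tested with camera (limma 3.58.1) on voom values at an inter-gene correlation of 0.01, and 87 tests were adjusted together. Camera was repeated with a correlation estimated from the residuals, and fry was run as an alternative; fry asks whether a list's genes move one way on balance, not whether they differ from other genes. In 2 lists, 4 members found no identifier: ERVI-1, ERVPABLB-1, H3C2 and H3C3. Some lists share members, so their calls are not independent of each other. Some members of the lists are not reported here.

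The rule named TERT, then per contrast up to 10 genes in each direction with the largest log2 fold change among called genes with a mean log2 CPM of at least 1, a gene symbol that is not a clone, LOC, LINC, antisense or pseudogene name, and 3 libraries of one group all beyond the 3 of the other. It added up to 4 members with the smallest p from each list called by camera and from 7 immune and retroviral lists, and, for TERT-K626A against TERT-WT, the genes named for each construct against Vector. Genes that differed at least 4-fold in CPM between libraries of a group, at 1 CPM or more and with 0.1 CPM added, were marked after the counts of single genes had been seen.

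Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no filter, a filter of at least 1 CPM in 3 libraries, fits of the 2 groups compared, TERT left out of the scaling, the replicate number as a block, and each library left out in turn. Removing each library's trend on GC content and transcript length, and leaving out the genes marked for 4-fold differences within a group, were the 2 chosen after the data were seen. Shared controls were simulated in 20 sets of unchanged groups.

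The tests were tried on simulated data drawn from the real means, library sizes and dispersions, with 200 of 19983 genes changed. For TERT-WT against Vector, edgeR recovered 38.0% of genes changed by 0.3 on the log2 scale, 42.0% at 0.5, 80.0% at 1 and 90.0% at 2. The shares were 36.0%, 58.0%, 78.0% and 96.0% for TERT-K626A against Vector, and 40.0%, 54.0%, 80.0% and 92.0% for TERT-K626A against TERT-WT, among 19983 genes each. An adjusted p depends on how many genes change. The data gave 16, 5499 and 6586 calls in the 3 comparisons, so recovery there may be lower for TERT-WT against Vector and higher for the others. Of the genes called, 8.76%, 10.7% and 12.5% were unchanged ones in the 3 comparisons (12 of 137, 16 of 150 and 19 of 152). These shares were above the nominal one, so single calls close to the threshold may be less certain than their adjusted p. Each share comes from a single simulated set, so its spread is not known. With no gene changed, edgeR called a median of 3, 2 and 3 genes per set in the 3 comparisons over 20 sets of 19983 genes, and medians of 0.5, 0 and 0 without the genes marked for 4-fold differences within a group. A list raised by 0.3 on the log2 scale was called in all 3 comparisons with the preset and with an estimated correlation, and no other list was. Genes were drawn independently there, so this does not show how often lists of correlated genes would be called falsely. A GC trend put into TERT-K626A gave 4046 calls against Vector among 19983 unchanged genes, and 0 after its removal.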

Results

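U2OS is a human osteosarcoma line known to maintain its telomeres without telomerase. Per the labels, its cells were transfected for 48 h with an empty pcDNA3.1 plasmid (Vector), the same plasmid carrying wild-type TERT (TERT-WT), or one carrying a mutant (TERT-K626A). TERT is the catalytic subunit of telomerase. Each group had 3 libraries, 9 in all, and the series title places them in the question of whether TERT alters endogenous retroviruses and immune genes. Reads counted on genes ranged from 14851846 in TERT-K626A replicate 1 to 25375734 in Vector replicate 3, with a median of 22486919. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Each pair of libraries within a group differed by more than sampling noise, with a chi-square of 2.24 to 3.51 per gene. The first principal component, with 58.1% of the variance, separated TERT-K626A from the 6 other libraries, and the second, with 12.4%, separated Vector from TERT-WT.

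TERT RNA was nearly absent from Vector and abundant in both transfected groups. The gene (ENSG00000164362.19) lies on the minus strand of chromosome 5 at 1253147 to 1295069 (GRCh38). Vector libraries held 5, 5 and 9 TERT counts, or 0.263 ± 0.0761 CPM (SD, n = 3). TERT-WT reached 1500 ± 41.4 CPM (SD, n = 3) and TERT-K626A 2122 ± 126 CPM (SD, n = 3). The log2 fold change over Vector was 12.43 ± 0.09 (SE) for TERT-WT and 12.93 ± 0.09 (SE) for TERT-K626A, with edgeR adjusted p = 1.12e-29 and 3.93e-30. TERT RNA was 1.41-fold higher in TERT-K626A than in TERT-WT, a log2 difference of 0.50 ± 0.04 (SE; edgeR adjusted p = 1.29e-09), so the constructs were not compared at the same TERT level. Counts on the gene do not separate plasmid from chromosomal transcripts.

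**Figure D1:**
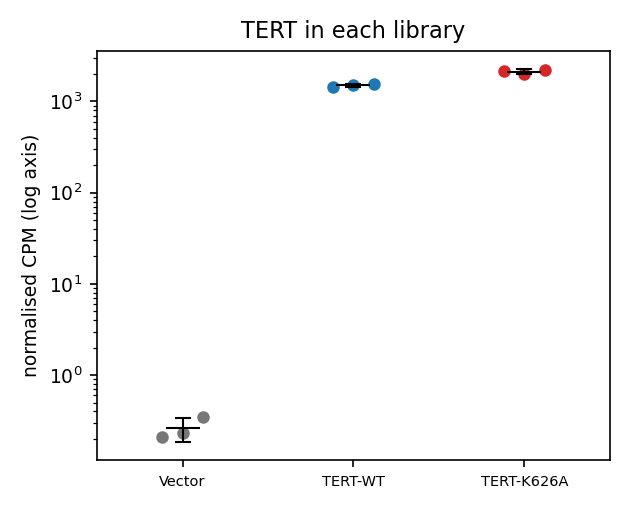
Normalised TERT level in CPM (log axis) in each of the 9 libraries, with 3 points per group and a bar for the mean with its SD. Vector lies at 0.263 CPM, TERT-WT at 1500 CPM and TERT-K626A at 2122 CPM.

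Wild-type TERT changed few genes against Vector, and the interferon-induced IFI6, IFI44L and IFI16 were among those that rose. IFI6 rose from 109 ± 5.32 to 161 ± 9.45 CPM (SD, n = 3; log2 fold change 0.56), and IFI44L rose from 11.03 ± 1.37 to 16.4 ± 1.56 CPM (log2 fold change 0.57). IFI16, a DNA sensor, rose by a log2 fold change of 0.25, the protease inhibitor A2M by 0.41, the secreted glycoprotein CHI3L1 by 0.37 and the hyaluronan synthase HAS2 by 0.30. HSPA6, a heat-inducible HSP70 gene, rose 3.90-fold, from 1.14 ± 0.140 to 4.45 ± 0.235 CPM. The tight-junction gene TJP1 fell from 17.1 ± 5.002 to 8.96 ± 0.598 CPM and SPRR2D, a cornified-envelope gene, from 23.8 ± 2.01 to 15.7 ± 1.19 CPM. In all, 12 of 19983 tested genes were higher and 4 lower at an edgeR adjusted p under 0.05, against 1193 at an unadjusted p under 0.05. The other calls, named after their values were seen because the rule left them out, were SMG1P5, MARF1 and VARS1 among the higher genes and MPO and MRM1 among the lower ones. HRAS and the transfected gene TERT itself completed the higher genes. HRAS, MARF1, VARS1 and MRM1 differed at least 4-fold between libraries of a single group, and 8 higher and 3 lower genes were called without such genes. Simulated without any change, 20 sets gave a median of 3 calls, from 0 to 8, and a median of 977 genes at an unadjusted p under 0.05. With 1 library left out, IFI44L, CHI3L1, HRAS and MARF1 were called in 2 of 6 edgeR fits, HAS2, IFI16 and MRM1 in 1, MPO in 3 and SMG1P5 and VARS1 in 4. HRAS, MARF1, VARS1 and MRM1 were not called by limma-voom (adjusted p = 0.762, 0.402, 0.839 and 0.452, the highest of their alternatives), nor MRM1 in a fit of the 2 groups (edgeR adjusted p = 0.0641), nor HAS2 without the genes that differed 4-fold within a group (edgeR adjusted p = 0.0552). The highest edgeR adjusted p was 0.335 for IFI44L and 0.317 for HAS2 without Vector replicate 2, and 0.114 for CHI3L1 without TERT-WT replicate 3. It was 0.201 for IFI16 without Vector replicate 1 and 0.173 for HRAS without Vector replicate 2. Higher genes numbered 7 without Vector replicate 1 and 5 without Vector replicate 2. Lower genes numbered 10 without Vector replicate 3 and 2 without TERT-WT replicate 2.

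Of 48 tested interferon-stimulated genes 42 had a log2 fold change above 0 in TERT-WT against Vector and 6 below, with a median of 0.19. Of the 48, 2 rose and 0 fell by edgeR over all genes tested (5 rose by DESeq2, and 26 had an unadjusted p under 0.05), and 23 rose and 0 fell adjusted over the list alone. ISG15 had a log2 fold change of 0.34 with edgeR adjusted p = 0.0948, and DESeq2 called it (adjusted p = 0.0148, over alternatives from 2.11e-07 to 0.517). Camera gave the list an adjusted p = 9.66e-25, and an adjusted p = 0.120 with an estimated correlation. The nucleic acid sensing list was also called upward (median 0.03, 1 of 19 members rose, also 1 adjusted over the list alone; adjusted p = 0.00197, and adjusted p = 0.175 with an estimated correlation), a call lost without TERT-WT replicate 3 (adjusted p = 0.0977). Some of its members also belong to the list of interferon-stimulated genes, so it is not a separate result. Mesenchymal and extracellular matrix genes were called upward by 0.04 in the median with no member passing over all genes (2 rose and 1 fell adjusted over the list alone; adjusted p = 0.0181, and adjusted p = 0.359 with an estimated correlation), a call lost without Vector replicate 2 (adjusted p = 0.306) and without TERT-WT replicate 2 (adjusted p = 0.104). Cytosolic ribosomal proteins (median -0.05; adjusted p = 4.80e-13, and adjusted p = 0.220 with an estimated correlation) and nuclear oxidative phosphorylation genes (median -0.05; adjusted p = 5.92e-05, and adjusted p = 0.183 with an estimated correlation) were called downward. Also called downward were the unfolded protein response and integrated stress response (median -0.05; adjusted p = 2.10e-04, and adjusted p = 0.289 with an estimated correlation) and MYC targets (median -0.05; adjusted p = 8.85e-04, and adjusted p = 0.288 with an estimated correlation). In those 4 downward lists 0 members passed edgeR's test over all genes (0 also by DESeq2, with 9, 5, 6 and 4 at an unadjusted edgeR p under 0.05). Adjusted over the list alone, 1 oxidative phosphorylation gene, ATP5MC1 (log2 fold change -0.21), did.

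In TERT-K626A against Vector, SAA1, SAA2, IL1B and CXCL5 were among the named genes that rose furthest. SAA1, an acute-phase protein gene, rose from 11.6 ± 0.497 CPM with a log2 fold change of 2.16, and its near-identical neighbour SAA2, whose reads may be split with it, had 2.23. The cytokine IL1B rose by 2.11, the neutrophil chemokine CXCL5 by 2.02, the IL-33 receptor IL1RL1 by 1.71, the elastase inhibitor PI3 by 1.68 and the matrix metalloproteinase MMP3 by 1.61. HSPA6 rose 7.98-fold. Among the genes that fell furthest were the neuropeptide gene UCN2 (log2 fold change -2.57), the nuclear receptor NR2F1 (-1.53), the granzyme GZMA (-1.46), SLITRK6 (-1.44), coagulation factor F5 (-1.32), the urea transporter SLC14A1 (-1.29), TBC1D10C (-1.27), the retrotransposon-derived PEG10 (-1.25) and A2M (-1.22). METRNL fell by 2.55 on the log2 scale, with Vector at 7.397 ± 5.04 CPM (SD, n = 3), and by 1.83 without Vector replicate 3, still called (adjusted p over its alternatives 4.61e-35 to 0.00310). EIF3CL and RNH1 were also called higher, but both differed at least 4-fold between TERT-K626A libraries, and EIF3CL had 832 counts in replicate 2 against 32 and 50 in the others, with no call when that library was left out (log2 fold change 0.38, adjusted p = 0.323).

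**Figure D2:**
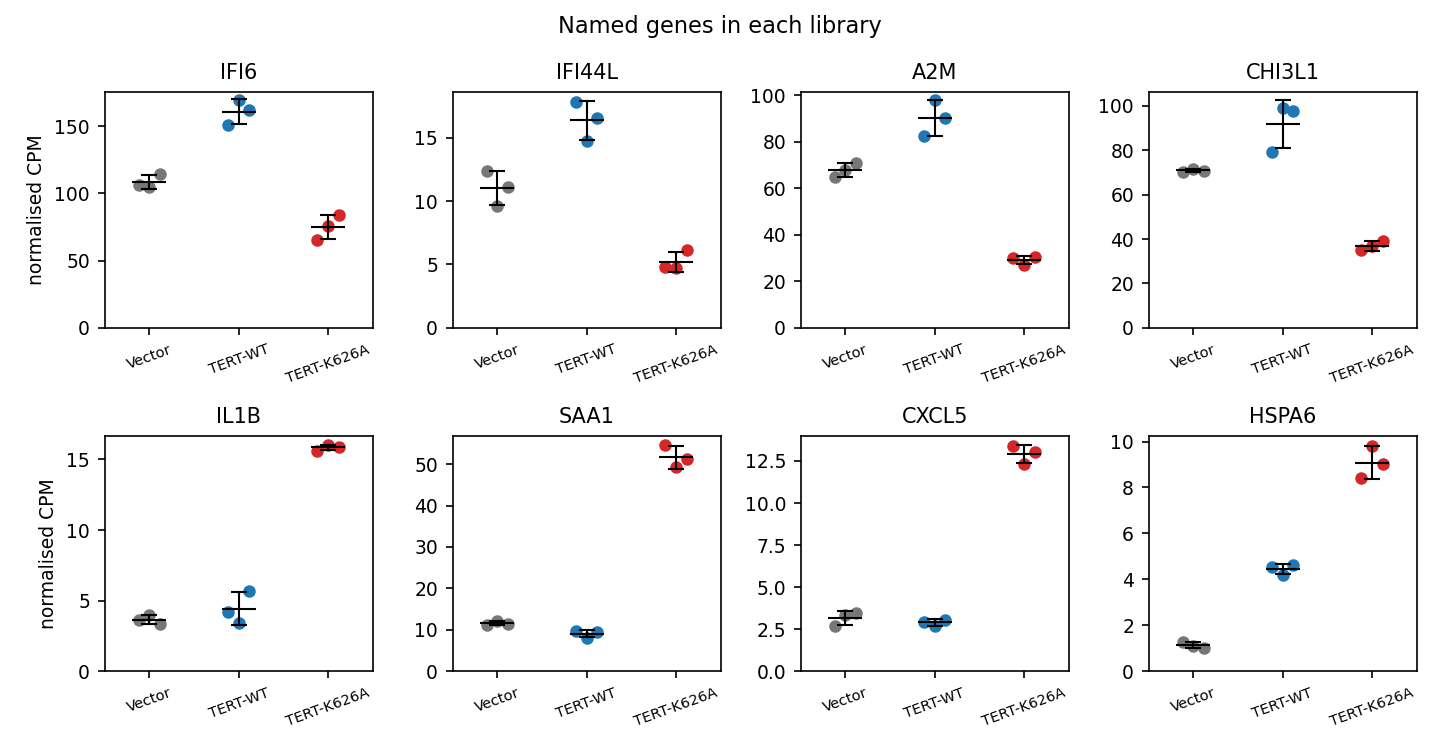
Normalised levels in CPM of 8 named genes in each of the 9 libraries, with 3 points per group and a bar for the mean with its SD, on linear axes from 0. IFI6, IFI44L, A2M and CHI3L1 are highest in TERT-WT and lowest in TERT-K626A, and IL1B, SAA1, CXCL5 and HSPA6 are highest in TERT-K626A.

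The changes in TERT-K626A were many and mostly small. Of 19983 genes, 2835 were higher and 2664 lower than in Vector (27.5%), with a median absolute log2 fold change of 0.30, and 150 higher and 273 lower genes changed at least 2-fold. NF-kB targets had the highest median log2 fold change of the 29 lists, 0.51. Of 24 members 17 rose and 3 fell, the same counts as adjusted over the list alone, and the smallest p-values were those of the apoptosis inhibitor BIRC3 (1.51), CCL20 (1.43), CXCL8 (1.39) and the superoxide dismutase SOD2 (0.85). Camera gave adjusted p = 4.80e-13, and adjusted p = 0.120 with an estimated correlation. Chemokines were called upward with 5 of 11 members rising and 1 falling in both adjustments, although the median was -0.01 (0.0041 with GC and length trends removed) and the mean 0.52 (adjusted p = 0.00396, and adjusted p = 0.167 with an estimated correlation). That list shares members with the NF-kB targets, CCL20 and CXCL8 among them, so the calls overlap. Of 14 immune checkpoint ligands and immunosuppressive factors 7 rose and none fell (8 rose and 1 fell adjusted over the list alone), among them CD274, which encodes PD-L1 (0.38), NECTIN2 (0.29), CD47 (0.33) and ARG2 (0.34). That list had a median of 0.23 (camera adjusted p = 0.00270, and adjusted p = 0.120 with an estimated correlation).

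Interferon-stimulated genes moved the other way. Of 48 tested, 21 fell and none rose (24 fell and 2 rose adjusted over the list alone), with a median of -0.20, including IFI44L (-1.08), IFIT1 (-0.55), IFI6 (-0.52) and PARP14 (-0.27). Camera gave an adjusted p = 1.45e-05, and an adjusted p = 0.220 with an estimated correlation. TLR3, a sensor of double-stranded RNA, fell by 1.22 on the log2 scale and the RNA editor ADAR by 0.14, and the nucleic acid sensing list was not called (2 of 19 fell, also 2 adjusted over the list alone; adjusted p = 0.485). In the list of interferons and their receptors the 6 tested members were all receptors, so no interferon gene was tested. IFNAR1 was the 1 that fell (-0.27), and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.812).

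Camera also called the heat shock, unfolded protein response, cholesterol, immediate early, ribosomal protein and oxidative phosphorylation lists upward in TERT-K626A against Vector. HSPA1A and HSPA1B had at most 2 counts in a library and were not tested, nor was HSPA4L with 1 to 8. HSPA1A and HSPA1B lie between HLA-F and TAPBP on chromosome 6, where 138 of 149 protein-coding genes had under 1 CPM on average, so their counts need not reflect their expression. For the heat shock response 13 of 17 rose and none fell (14 adjusted over the list alone), with DNAJB1 at 0.64 and HSPH1 at 0.58 (median 0.27; adjusted p = 2.90e-11, and adjusted p = 0.120 with an estimated correlation). The unfolded protein response and integrated stress response list had 18 of 30 rising and 4 falling (20 and 4 adjusted over the list alone), with the smallest p-values for the chaperone HSPA5 at 0.59, SDF2L1 at 0.52 and HERPUD1 at 0.43 (median 0.14; adjusted p = 1.43e-05, and adjusted p = 0.226 with an estimated correlation). In cholesterol and fatty acid synthesis 13 of 21 rose and 1 fell (14 and 1 adjusted over the list alone), with SQLE at 0.65 (median 0.28; adjusted p = 1.64e-09, and adjusted p = 0.134 with an estimated correlation). Immediate early genes had 12 of 22 rising and 2 falling (12 and 3 adjusted over the list alone), CCN1 at 0.73 and JUN at 0.49 rising and EGR1 at -0.63 falling (median 0.19; adjusted p = 2.11e-04, and adjusted p = 0.120 with an estimated correlation). Among ribosomal proteins 32 of 45 rose and none fell (37 adjusted over the list alone; median 0.13, RPL4 at 0.21; adjusted p = 1.21e-13, and adjusted p = 0.220 with an estimated correlation). Nuclear oxidative phosphorylation genes had 8 of 34 rising, also 8 adjusted over the list alone (SDHB at 0.28, median 0.07; adjusted p = 0.00615, and adjusted p = 0.292 with an estimated correlation). With GC and length trends removed their median was 0.03 (adjusted p = 0.0415, over alternatives from 7.36e-05 to 0.292). Mitochondrially encoded genes were called downward, with 5 of 13 falling and MT-ND4 rising in both adjustments (median -0.08; adjusted p = 0.0257, and adjusted p = 0.359 with an estimated correlation), a call lost without Vector replicate 1 (adjusted p = 0.0860) and without Vector replicate 2 (adjusted p = 0.0502). With GC and length trends removed their median was -0.15 (adjusted p = 0.00113, over alternatives from 1.09e-04 to 0.359).

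The cell cycle list divided by phase. All 19 of its G2 and mitosis members rose, with a median log2 fold change of 0.41, and the smallest p-values were those of the ubiquitin-conjugating enzyme UBE2C (0.54), the spindle checkpoint kinase BUB1 (0.62), CDC20 (0.48) and the cyclin CCNA2 (0.51). Of its 16 G1/S and replication members 10 fell and none rose, with a median of -0.21, including TYMS (-0.59), CDC45 (-0.38) and MCM3 (-0.26), which were named, like the division itself, after the values were seen. As a whole, 19 members rose and 10 fell (19 and 12 adjusted over the list alone; median 0.20; camera adjusted p = 0.00142, and adjusted p = 0.120 with an estimated correlation).

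No tested gene derived from or initiated in endogenous retroviruses was called higher in either construct. Of 18 members found in the annotation 9 were tested, and some had few counts. ERVK9-11 had 5 to 35 per library and ERVW-1 16 to 45, so a moderate rise could be missed. Reads that did not align uniquely were counted on no gene, so reads matching several retroviral copies are not in these counts. Of 9 tested members 0 passed edgeR's test in TERT-WT against Vector (0 also by DESeq2, and 1 at an unadjusted p under 0.05), where ERVK9-11 had 0.65 (adjusted p = 0.809) and ERVW-1 0.40 (adjusted p = 0.868). In TERT-K626A 1 member, ERVK13-1, fell (-0.50; adjusted p = 1.35e-05), also adjusted over the list alone. ERVK9-11 (-0.98; adjusted p = 0.0526) was called lower with the stricter filter, with GC and length trends removed, without Vector replicate 2 (0.0448) and without TERT-K626A replicate 2 (0.0490), over alternatives from 0.0399 to 0.188. ERV3-1 (-0.29; adjusted p = 0.0632) was called lower with those trends removed (0.0408; alternatives up to 0.190), and ERVW-1 (-0.51; adjusted p = 0.187) without TERT-K626A replicate 1 (0.0398; alternatives up to 0.562). Camera did not call the list in TERT-WT (adjusted p = 0.477) or TERT-K626A (adjusted p = 0.107), and retroviral loci outside annotated genes were not analysed here. Of 32 genes that silence endogenous retroviruses 5 rose and 8 fell in TERT-K626A (6 and 8 adjusted over the list alone), with the DNA methyltransferase DNMT3B at 0.37 and the heterochromatin protein CBX5 at -0.24, and 0 passed in TERT-WT by edgeR or DESeq2 (1 at an unadjusted p under 0.05).

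Apart from MYC targets and mesenchymal and extracellular matrix genes in TERT-WT, the other lists were called in neither construct against Vector. In TERT-K626A against Vector, 2 of 11 tested antigen presentation genes rose, PSME2 (0.19) and ERAP1 (0.18). TAP1 and PSMB9, in the same interval of chromosome 6 as HSPA1A, averaged 0.00488 and 0.0106 CPM and were not tested. Of 18 telomerase partners and shelterin genes 4 rose and 2 fell, of 22 genes of alternative lengthening of telomeres 4 rose and 6 fell, of 18 Wnt and beta-catenin targets 2 rose and 4 fell and of 29 MYC targets 7 rose and 5 fell. These counts and those for antigen presentation were unchanged when adjusted over the list alone. Of 28 p53 targets 11 rose and 7 fell (11 and 9 adjusted over the list alone). Of 27 hypoxia and glycolysis genes 7 rose and 5 fell (10 and 5 adjusted over the list alone). The p53 targets had a median of -0.04 and a mean of -0.02 while camera pointed upward (adjusted p = 0.737). Mesenchymal and extracellular matrix genes, called in TERT-WT alone, had 8 of 25 rising and 9 falling (9 and 9 adjusted over the list alone), with a positive median of 0.04 and a downward camera direction (adjusted p = 0.949). Replication-dependent histones had 5 of 15 falling (6 adjusted over the list alone; adjusted p = 0.0610). With GC and length trends removed, camera called them downward in TERT-K626A (adjusted p = 0.0424, over alternatives from 0.00434 to 0.327) and upward in TERT-WT (adjusted p = 0.0336, over alternatives from 0.0135 to 0.511). Osteoblast lineage markers had 1 rising and 3 falling of 8 (1 and 5 adjusted over the list alone). Epithelial markers had 1 rising and 2 falling of 12, the same as adjusted over the list alone. Of 6 leukocyte markers CORO1A rose (1 rose and 2 fell adjusted over the list alone). Of 11 endothelial markers ROBO4 rose (0 adjusted over the list alone). DESeq2 did not call CORO1A (adjusted p = 0.0704, over alternatives from 0.0158 to 0.118) or ROBO4 (adjusted p = 0.0690, over alternatives from 0.0176 to 0.203), and with 1 library left out edgeR called CORO1A in 0 of 6 fits and ROBO4 in 2. In TERT-WT against Vector, the chemokines had a median of -0.0031, a mean of 0.0254 and an upward camera direction. The checkpoint list had a median of 0.0025, a mean of 0.057 and a downward one, and the Wnt list a median of -0.0061, a mean of -0.0037 and an upward one, with no call for any of the 3. Among lists not called there, adjusted over the list alone 1 chemokine gene rose and 1 fell, and 1 cell cycle gene and 1 immediate early gene fell.

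**Figure D3:**
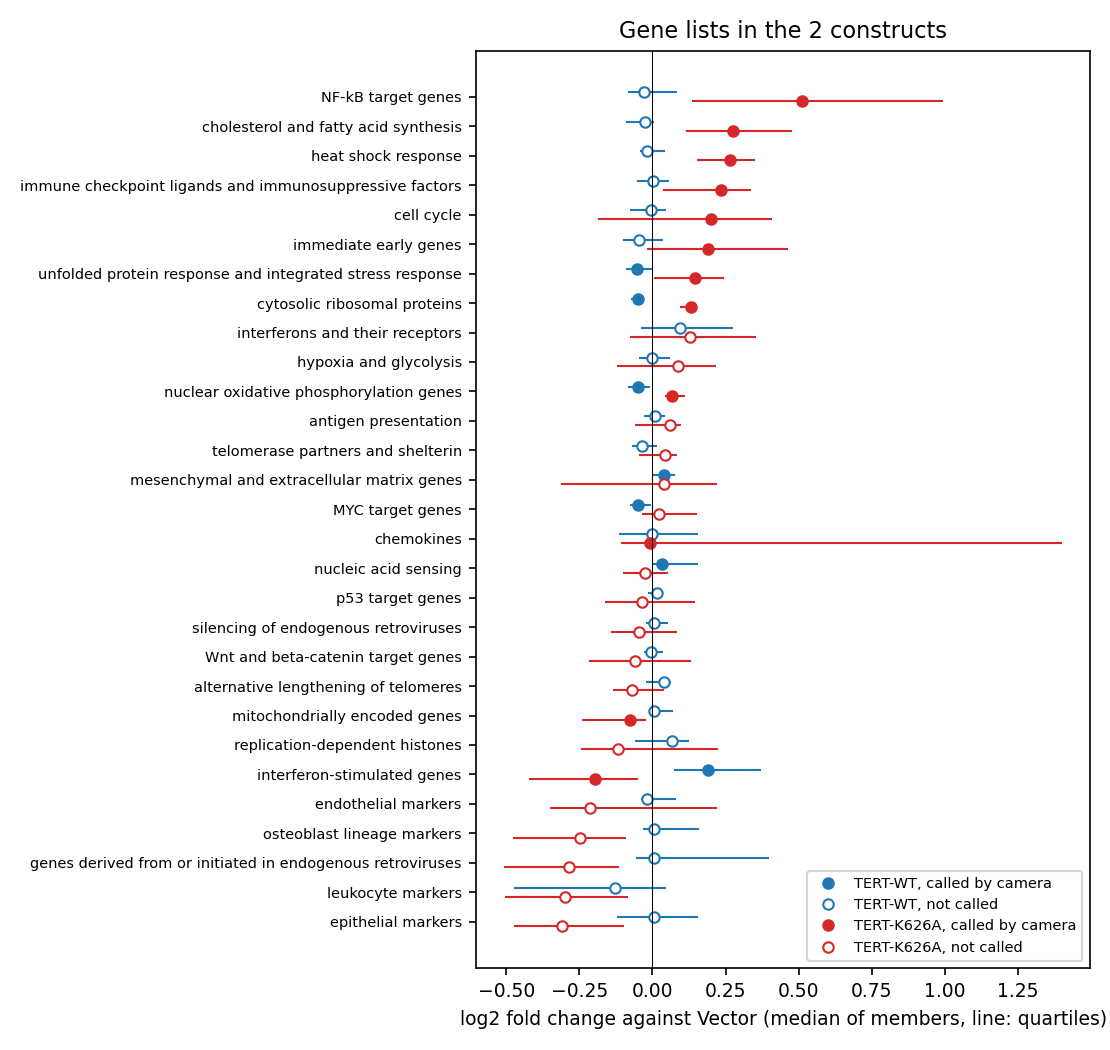
Median log2 fold change against Vector of each of the 29 gene lists in TERT-WT (blue) and TERT-K626A (red), with lines from the lower to the upper quartile of members and filled points where camera with a preset correlation called the list. Interferon-stimulated genes lie at 0.19 in TERT-WT and -0.20 in TERT-K626A, and NF-kB targets at 0.51 in TERT-K626A.

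Compared directly, TERT-K626A stood below TERT-WT in interferon-stimulated genes and above it in NF-kB targets. Of 48 interferon-stimulated genes 31 fell and none rose (35 fell adjusted over the list alone), with IFI44L at -1.64, IFI6 at -1.09, IFIT1 at -0.92 and PARP14 at -0.44. The median was -0.40 (camera adjusted p = 2.92e-12, and adjusted p = 0.120 with an estimated correlation). EIF3CL (2.48) was called higher with edgeR adjusted p = 0.00538 but not without TERT-K626A replicate 2 (-0.23; adjusted p = 0.535, the highest of its alternatives). Apart from it, SAA2 (2.61), SAA1 (2.49), CXCL5 (2.15), IL1RL1 (2.05), the growth factor CSF2 (1.89), MMP3 (1.84), IL1B (1.83), SPRR2D (1.81), MMP1 (1.66) and CCL20 (1.62) had the highest log2 fold changes of the named genes. UCN2 (-2.98), GZMA (-2.22), NR2F1 (-1.93), SLITRK6 (-1.89), A2M (-1.63), SLC14A1 (-1.63), TLR3 (-1.59), HAS2 (-1.49) and CHI3L1 (-1.31) were lower, and TJP1 showed no call (-0.03; adjusted p = 0.913). IFI27L1 and METRNL were called lower too, IFI27L1 with at least 4-fold differences within a group and METRNL without a call when TERT-WT replicate 2 was left out (edgeR adjusted p = 0.0527). Altogether 3406 genes were higher and 3180 lower (33.0% of 19983), 188 and 405 of them at least 2-fold.

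The lists called between the constructs were the 12 called in TERT-K626A against Vector, in the same directions, and replication-dependent histones. NF-kB targets had 17 members rising and 3 falling (median 0.59; camera adjusted p = 3.74e-11, and adjusted p = 0.120 with an estimated correlation). The heat shock response had 13 and 0 (0.28; adjusted p = 1.38e-09, and adjusted p = 0.134 with an estimated correlation), both the same as adjusted over the list alone. Checkpoint ligands and immunosuppressive factors had 7 rising and 1 falling, also adjusted over the list alone (0.27; adjusted p = 0.00536, and adjusted p = 0.134 with an estimated correlation). The unfolded protein response had 19 rising and 5 falling (21 and 5 adjusted over the list alone; median 0.21; adjusted p = 5.10e-07, and adjusted p = 0.195 with an estimated correlation). Cell cycle genes had 19 and 12 (20 and 14 adjusted over the list alone; 0.22; adjusted p = 0.00458, and adjusted p = 0.120 with an estimated correlation). Cholesterol genes had 15 rising and 0 falling (15 and 1 adjusted over the list alone; 0.33; adjusted p = 2.29e-09, and adjusted p = 0.134 with an estimated correlation). Immediate early genes had 12 and 3 (14 and 4 adjusted over the list alone; 0.19; adjusted p = 2.19e-04, and adjusted p = 0.120 with an estimated correlation). Oxidative phosphorylation genes had 16 rising and 0 falling, also adjusted over the list alone (0.11, and 0.07 with GC and length trends removed; adjusted p = 6.24e-05, and adjusted p = 0.183 with an estimated correlation). Ribosomal proteins had 39 and 0 (40 and 1 adjusted over the list alone; 0.18; adjusted p = 2.05e-18, and adjusted p = 0.167 with an estimated correlation). The list of chemokines was called upward with a median of -0.02 (-0.07 with GC and length trends removed) and a mean of 0.49 (5 rose and 3 fell, also adjusted over the list alone; adjusted p = 0.0315, and adjusted p = 0.220 with an estimated correlation). That call was lost without TERT-WT replicate 1 (adjusted p = 0.0573) and replicate 3 (adjusted p = 0.0590), and with the stricter filter (adjusted p = 0.0525). The mitochondrially encoded genes were called downward (2 rose and 5 fell, also adjusted over the list alone; -0.13, and -0.23 with GC and length trends removed; adjusted p = 0.0229, and adjusted p = 0.359 with an estimated correlation), a call lost without TERT-WT replicate 3 (adjusted p = 0.0591). Replication-dependent histones were called downward too (7 fell, also adjusted over the list alone, with H2AC6 at -0.59 and H4C8 at -0.92; -0.22; adjusted p = 0.0251, and adjusted p = 0.289 with an estimated correlation). Among lists not called, the p53 targets had a median of -0.02 and a mean of -0.03 with an upward camera direction, and the Wnt targets a median of -0.10 and a mean of 0.0015 with a downward one. Antigen presentation had a median of 0.0104 and a mean of -0.0046 with an upward direction. The list of interferons and their receptors, of which only receptors were tested, had a median of 0.138 and a mean of 0.0119 with a downward direction. Of the retrovirus-derived genes ERVK13-1 (-0.44), ERVK9-11 (-1.62) and ERVW-1 (-0.90) were lower in TERT-K626A than in TERT-WT, with camera adjusted p = 0.0797 for the list (0.0418 without TERT-WT replicate 2, over alternatives from 0.00340 to 0.312) and no call for ERVW-1 without TERT-WT replicate 2 (edgeR adjusted p = 0.0610), TERT-K626A replicate 2 (0.0566) or TERT-K626A replicate 3 (0.0895).

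Of the 16 genes called in TERT-WT against Vector, 6 were also called in TERT-K626A in the same direction and 6 in the opposite one. TERT, HSPA6 and SMG1P5 were higher in both and MPO, TJP1 and MRM1 lower in both. Of these, TERT was transfected in both groups and MRM1 differed at least 4-fold between libraries of a group. SMG1P5 did not, but it lies on chromosome 16 next to NPIPB13, which did. The count of 6 therefore includes genes that say little about a response common to the constructs. By contrast, IFI6, IFI44L, A2M, CHI3L1, HAS2 and SPRR2D were called in opposite directions. Independent lists of these sizes would share 1.70 higher and 0.533 lower genes, with 1.60 higher in TERT-WT and lower in TERT-K626A. Unchanged groups simulated against the same controls shared at most 1 in the same direction. Those simulated groups had a median of 2 genes called for TERT-K626A, so their overlap sets no scale for the 6 genes observed. Across 14461 genes, which are not independent replicates, the log2 fold changes correlated with r = -0.10, against 0.483 for unchanged groups sharing the Vector libraries. In those simulated groups the fold changes are noise alone. In the data 27.5% of genes were called in TERT-K626A against Vector, which by itself can weaken r, so 0.483 is no level to expect. The correlation in the data was 0.0163 without Vector replicate 1, -0.0082 without Vector replicate 2, -0.0411 without Vector replicate 3 and -0.0353 without TERT-WT replicate 2. The genes called in 1 direction by both numbered 3, not 6, without TERT-WT replicate 2. The covariance was -0.00312 against a simulated 0.00643, a difference of -0.00955. The 3 Vector libraries cannot be split into parts of at least 2 each, so part of the overlap may come from the shared controls.

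**Figure D4:**
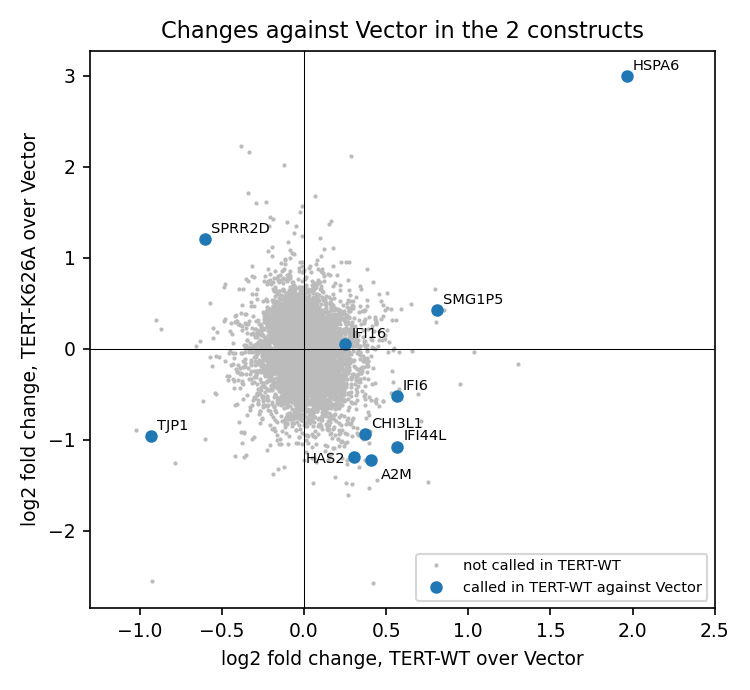
Log2 fold change of each gene against Vector in TERT-WT (horizontal) and TERT-K626A (vertical), for genes with a mean log2 CPM of at least 1, without TERT and without genes that differed at least 4-fold within a group. Blue points are genes called in TERT-WT, among which HSPA6 rose in both constructs while IFI6, IFI44L, A2M, CHI3L1 and HAS2 lie below 0 for TERT-K626A.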

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

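The tests on the amount of TERT RNA, the shared Vector libraries, separate cultures, low counts, neighbouring genes and near-identical copies were chosen after the results were seen, and the removal of GC and length trends was chosen after the data were seen. Camera with a preset correlation called 4 gene lists in opposite directions in the constructs against Vector and also between the constructs, and all 12 of these calls were lost with an estimated correlation (adjusted p = 0.120 to 0.292). The median log2 fold changes of TERT-K626A over TERT-WT were -0.40 for interferon-stimulated genes, 0.21 for the unfolded protein response and integrated stress response, 0.11 for nuclear oxidative phosphorylation genes and 0.18 for cytosolic ribosomal proteins. With GC and length trends removed the oxidative phosphorylation difference was 0.07.

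Interferon-stimulated genes were called higher as a list in TERT-WT and lower in TERT-K626A, calls lost with an estimated correlation (adjusted p = 0.120 and 0.220). A response that grows with TERT RNA would move members the same way in both constructs. The 16 members that edgeR called against Vector in both, adjusted over the list alone, went in opposite directions. The list was flagged for its opposite calls, so that count restates the pattern and cannot exclude the amount of TERT RNA as a cause. A shift in the shared Vector libraries does not enter the log2 fold change of TERT-K626A over TERT-WT. There 31 of 48 members were called lower by edgeR over all genes. The difference between the constructs thus does not rest on Vector. The opposite directions against Vector do, so such a shift stays open for them. After each library's trend on GC content and length was removed, the list kept at least 101% of its median in either construct. A single culture or preparation per group also stays open, and a difference between the 2 TERT proteins may be an explanation but is an untested hypothesis.

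In TERT-K626A 5499 genes changed against Vector, with a median absolute log2 fold change of 0.30, which technical differences could give. With the GC and length trends removed, 6097 genes were called against Vector, not fewer than before. Without the shallowest library, TERT-K626A replicate 1, 4505 genes were called. A culture, transfection or library preparation made once per group cannot be told apart from the construct, since the labels do not say and the common coefficient of variation was only 4.68%. The design names the mutant TERT as the biological difference, untested against that.

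Between libraries of 1 group, 116 genes differed at least 4-fold. Their median share of exonic length shared with other genes was 0%, as for all tested genes, which argues against shared exons as the cause of the whole set. Single genes did share exons, such as ATP5ME with 61.6%, so that cause stays open for them. Counting noise acts on each gene alone. Low counts as the whole cause would thus not place 62.1% of these genes within 1 Mb of another, against at most 27.6% in 1000 random sets with the same spread of highest counts. Low counts stay open for the 44 genes with no other within 1 Mb, whose position says nothing on it. The share of 62.1% also exceeded the highest of 1000 random sets of tested genes (32.8%), as regions with a second copy in the alignment reference may give, and 28.4% shared most of their 50-base words with another annotated gene, a share that leaves copies among annotated genes open. From HLA-F to TAPBP on chromosome 6 (29722775 to 33314387), 138 of 149 protein-coding genes had under 1 CPM on average (92.6%, against 36.9% on the rest of the chromosome), among them RPS18 at 0.0241 CPM, where the other ribosomal protein genes had a median of 871, and no biological explanation was tested.

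Fits of only the 6 libraries compared were also run on their other splits into 3 and 3, and 10 splits are too few for a share under 0.05. The real split, the 1 split with as many, gave 18 genes for TERT-WT against Vector with a highest other of 12, 5462 for TERT-K626A against Vector with 1, and 6416 for TERT-K626A against TERT-WT with 1. Each other split mixes the groups on both sides, so any difference between them widens its spread and lowers its calls. Its counts are therefore no null level.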

How the results depend on the processing

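The removal of GC and length trends and the fit without genes that differed 4-fold within a group were chosen after the data were seen. EIF3CL was the 1 named gene that reversed, with a log2 fold change of -0.2333 between constructs without TERT-K626A replicate 2 and 3.01 without replicate 3, and TERT kept its direction and its call under every setting. The small TERT-WT counts moved most: 53 higher and 41 lower genes with no filter, 28 and 13 with GC and length trends removed, and 2 lower with the stricter filter; the cause was not tested. Leaving out 1 library gave 5 to 13 higher and 2 to 10 lower genes for TERT-WT, 2211 to 2528 and 1954 to 2314 for TERT-K626A against Vector, and 2804 to 3199 and 2626 to 2902 for TERT-K626A against TERT-WT. In those fits HRAS, IFI44L, CHI3L1, HAS2, IFI16, MARF1, MRM1, MPO, SMG1P5 and VARS1 lost their TERT-WT call at least once, EIF3CL lost its TERT-K626A call without replicate 2 (adjusted p = 0.323), and A2M, HSPA6, IFI6, SPRR2D and TJP1 were called in all 6. Between constructs METRNL was lost with limma-voom (adjusted p = 0.0746) and IFI27L1 with DESeq2 (adjusted p = 0.0607), HRAS with DESeq2 (0.0985) and limma-voom (0.114), RNH1 with DESeq2 (0.0746) and without TERT-K626A replicate 2 (0.138), and EIF3CL with limma-voom (0.185), and EIF3CL in TERT-K626A against Vector with limma-voom (adjusted p = 0.0984). Genes called in both constructs in 1 direction numbered 6, 3 with DESeq2, 28 with no filter and 3 to 8 with 1 library left out. The correlation of log2 fold changes was -0.10 and ranged from -0.14 to 0.02 with 1 library left out, with 0.0163 without Vector replicate 1, so its sign turned without that library. With an estimated correlation 0 lists were called in each of the 3 contrasts, in place of 7, 12 and 13. With GC and length trends removed 8, 13 and 13 were called. Fry called 2, 17 and 20, among them the retrovirus-derived list downward in TERT-K626A against Vector (adjusted p = 0.00662) and against TERT-WT (adjusted p = 0.00340), and 1 library left out gave 7 to 10, 11 to 13 and 11 to 15. Some lists without a camera call in the fit of all 9 libraries gained one with 1 library left out. In TERT-WT these were telomerase partners and shelterin downward without Vector replicate 3 (adjusted p = 0.0362) and TERT-WT replicate 2 (0.00811), and hypoxia and glycolysis downward without Vector replicate 2 (0.0274) and TERT-WT replicate 2 (0.0210). Without TERT-WT replicate 2, immediate early genes (0.0274) were also called downward and mitochondrially encoded genes (0.00499) upward. Without TERT-WT replicate 3, NF-kB targets (0.00996) and cholesterol and fatty acid synthesis (0.0287) were called downward, and alternative lengthening of telomeres (0.0369) and histones (0.0135) were called upward without Vector replicate 2 and TERT-WT replicate 1. In TERT-K626A against Vector, histones were called downward without Vector replicate 2 (0.0370) and TERT-K626A replicate 3 (0.0423), and hypoxia and glycolysis upward without Vector replicate 3 (0.0105). Between constructs the calls gained were nucleic acid sensing downward (0.0461) and MYC targets upward (0.0244) without TERT-K626A replicate 3, and hypoxia and glycolysis upward (0.0268) and the retrovirus-derived list downward (0.0418) without TERT-WT replicate 2. The stricter filter added histones in both constructs and immediate early genes in TERT-WT (0.0307 each). No filter added telomerase partners (0.0177), immediate early (0.0300) and mitochondrially encoded genes (0.00693) in TERT-WT, hypoxia and glycolysis (0.0109) and histones (0.00657) in TERT-K626A, and nucleic acid sensing (0.0220), MYC targets (0.00436) and hypoxia and glycolysis (0.00748) between constructs. The replicate block added telomerase partners in TERT-WT (0.0408). The replicate numbers gave no sign of pairing the libraries. Of the 9 same-number pairs across groups 2 had a correlation of deviations over 0.1 (-0.164 to 0.176), and 3 libraries correlated best with their own number. Pairs with different numbers ranged from -0.238 to 0.236, so a pairing that the numbers do not mark stays open. The replicate block gave 14 higher and 6 lower genes in TERT-WT, 2898 and 2711 in TERT-K626A, and 3475 and 3230 between constructs. No scaling moved the median of all genes by 0.1. Among the 4996 tested genes with the lowest level the median SE of the log2 fold change of TERT-WT over Vector was 0.359, against 0.0457 among the 4996 with the highest, which limits what could be called among low genes.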

Other observations

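Matrix genes divided in TERT-K626A against Vector, and the members named here were chosen after their values were seen. The transcription factor ZEB1 (log2 fold change 0.62), tenascin TNC (0.41), the collagenase MMP1 (1.45) and vimentin VIM (0.31) rose, while TGFBI (-0.58) and the collagen genes COL1A1 (-0.36), COL3A1 (-0.60), COL5A1 (-0.25), COL5A2 (-0.38) and COL6A3 (-0.30) fell. In hypoxia and glycolysis, the lipase inhibitor ANGPTL4 (-1.05) and the oxygen sensor EGLN3 (-0.59) fell and BNIP3 (0.40) rose. Among genes of alternative lengthening of telomeres, ZNF827 (-0.57) fell and DAXX (0.92) rose, DAXX from 0.752 CPM to 1.39 CPM and with edgeR adjusted p = 0.0427. DAXX was not called by DESeq2 (adjusted p = 0.0791) or limma-voom (adjusted p = 0.0689), nor in 5 of the 6 edgeR fits with 1 library left out, with alternatives from 0.0149 to 0.331. DAXX lies on chromosome 6 next to the interval from HLA-F to TAPBP, where most protein-coding genes had few counts. Its counts therefore need not reflect its expression.

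MPO, which encodes a peroxidase of myeloid cells, had 20, 37 and 16 counts in the Vector libraries, 3, 0 and 1 in TERT-WT and 0, 0 and 1 in TERT-K626A.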
